A study of Mus musculus with 8 samples.

How the data were processed

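RNA from 8 pools of mouse outflow tracts, 4 tracts per pool, was measured on 1 slide of Agilent one-colour arrays (design 028005, 60-base probes placed on mm9). Per the labels, the wild type embryos were littermates of the mutants, and the food of the dams held 0.1 mg/g all-trans-retinoic acid; RNA was taken with columns without DNase, with an integrity number above 8, and 50 ng was labelled with Cy3. The authors deposited 1 scanner file per array from Agilent Feature Extraction 10.7.3.1 (protocol GE1_107_Sep09) and a matrix over all arrays. The deposited values are in the unit intensity, linear and not scaled between arrays: per the file headers, the processed signal had its background subtracted and was detrended within the array. The matrix equalled the processed signal rounded to 3 significant digits, with a largest difference of 0.496%. The file of knockout pool 1 held its signals to 3 significant digits, unlike the other 7.

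Of 59305 spots that are not controls, those of 1 probe were averaged, which gave 55681 probes. A probe was kept when it was well above background on at least 3 arrays of 1 group; 33438 were kept, of which 34 were lost because their spot was marked as unusable by the scanner software. Values were log2 processed signals minus the log2 of the array's 75th percentile. Probes took their gene name through their accession (26056 probes matched the reference table) or the name in the file, and the kept probe with the highest mean over the arrays stood for its gene, which left 24291 genes, 15134 with a symbol. Of 6278 genes with more than 1 kept probe, 36.2% held probes of opposite sign. The number of arrays limits the precision. Without wild type pool 1, a probe needed to be above background on at least 3 arrays of 1 group in the same way.

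Groups were compared, knockout minus wild type, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Aldh1a2 was tested beside this with an exact permutation test. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over 25 lists with at least 4 measured members; each list's genes were also adjusted over the list alone. The lists were fixed before the data were examined, as were the tests and most alternatives. They were retinoic acid signalling and responsive genes, second heart field, cardiomyocyte, cardiac neural crest and crest-derived mesenchyme, endothelial and endocardial, cushion mesenchyme and epithelial-mesenchymal transition, smooth muscle, epicardium, pharyngeal endoderm and surface epithelium, pharyngeal and head muscle mesoderm, neuronal, erythroid, macrophage and leukocyte, Hox genes, FGF, TGF-beta and BMP, Notch, Wnt and hedgehog signalling, semaphorin, slit and ephrin guidance, hypoxia and glycolysis, cell cycle, immediate early and stress, extracellular matrix and basement membrane, and ribosomal proteins. A sex-linked list was kept out of the set test. Of 634 genes in the lists, 36 stand in more than 1.

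Named genes followed a rule fixed before the data were examined: Aldh1a2; the 12 largest rises and falls among genes past the threshold without overlap between groups or, where fewer than 5 passed, the 5 with the smallest unadjusted p and no overlap; 2 members of each list with the smallest unadjusted p where none passed; and Rarb, Cyp26a1, Dhrs3, Tbx1, Fgf8, Fgf10, Isl1, Mef2c, Hand2, Tbx2, Wnt11, Sox10, Tgfb2, Bmp4, Acta2, Myh7 and Nppa. Some genes that the rule names are left out of the text. Genes named outside it are said to be chosen after their values were seen. The fit and set test were tested on simulated data with 200 changed genes. A list shifted by -0.5 was called in all 4 simulations and no other list was. The genes were simulated as independent, while the estimated correlation within a list reached 0.992 in the data (ribosomal proteins). The simulations therefore cannot show how often camera at the preset correlation calls a list falsely here. Alternatives were quantile and median scaling, normexp background (offset 50), the matrix values, the filter on dim probes, the mean of a gene's probes, single probes, a fold minimum of 1.5, eBayes with trend and robust, array weights, pool number or slide position as a block, a Y-linked covariate, leaving out each pool, camera with an estimated correlation, and fry. The matrix was linear, so its log2 was taken for that alternative.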

Results

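The data were 8 one-colour expression arrays of mouse outflow tracts, the part through which blood leaves the embryonic heart, microdissected at stage E10.5. Each array held RNA from a pool of 4 outflow tracts. Retinoic acid synthesis was disrupted by loss of Raldh2, now named Aldh1a2, the enzyme that makes retinoic acid from retinaldehyde in the embryo. The dams had been given all-trans-retinoic acid in their food from E7.5 to E8.5, so both groups are called rescued. There were 4 pools of rescued Raldh2-/- embryos (knockout pools 1, 2, 3 and 7) and 4 pools of rescued wild type embryos (wild type pools 1, 2, 5 and 7). The share of spots well above background was 61.1%, 61.6%, 61.3% and 63.2% on the arrays of knockout pools 1, 2, 3 and 7. It was 94.7%, 62.2%, 62.5% and 53.3% on those of wild type pools 1, 2, 5 and 7. The array of wild type pool 1 stood apart: its median processed signal was 2023, against 40.0 to 83.0 on the other 7, and its median correlation with the others across probes was 0.775, against 0.979 to 0.989. The counts, the lists and most named genes are therefore also given without that pool, a setting decided before the data were examined that gained this role after the arrays were seen. The number of arrays limits the precision of every value.

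**Figure D1:**
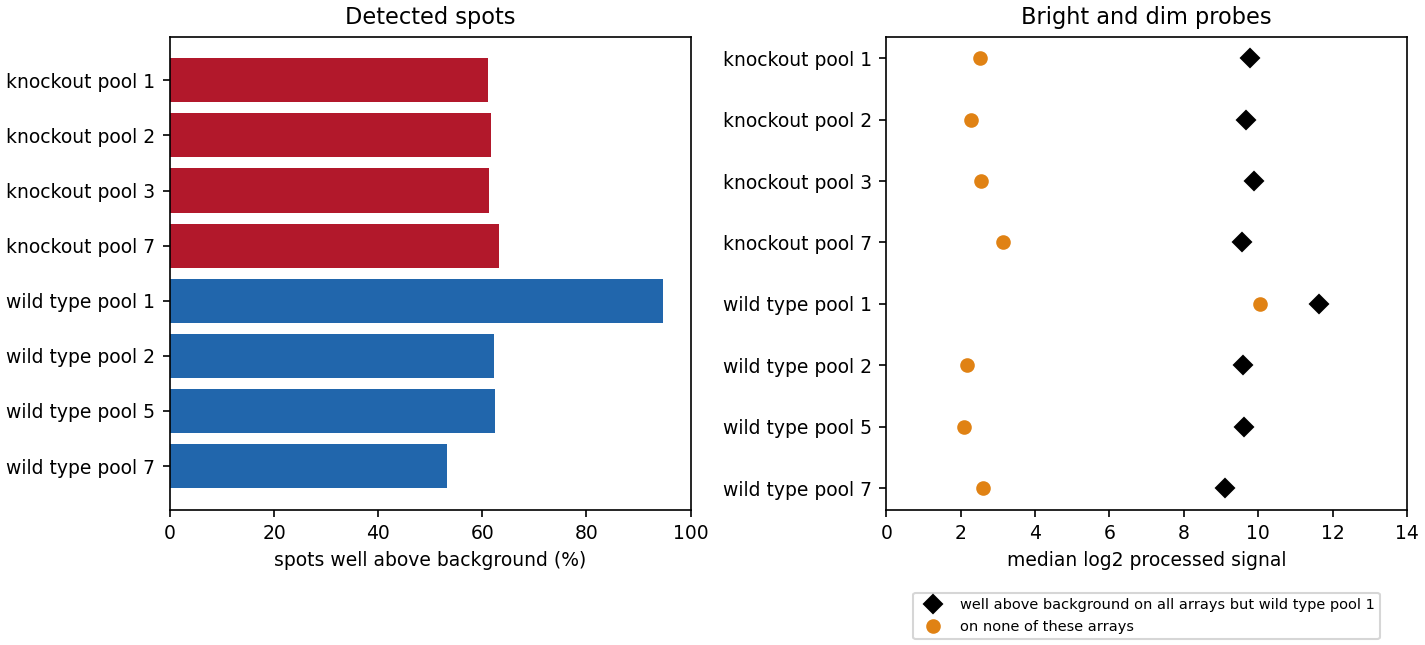
Left, share of spots well above background (%) on each array, in red for the knockout and in blue for the wild type pools. Right, median log2 processed signal of probes well above background on all 7 arrays other than wild type pool 1 (diamonds) and on none of them (circles); on wild type pool 1 the second median was 10.06, against 2.08 to 3.14 on the others.

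The comparison asked how expression in the outflow tract differs when the embryo's own retinoic acid synthesis is lost after an early rescue. Aldh1a2 itself was lower in the knockout pools. Its log2 signal relative to the array's 75th percentile was 2.02, 2.01, 1.87 and 0.059 in knockout pools 1, 2, 3 and 7, and 1.92, 3.21, 2.98 and 3.65 in wild type pools 1, 2, 5 and 7. The means were 1.49 ± 0.96 (SD, n = 4) and 2.94 ± 0.73 (SD, n = 4), a difference of -1.45 (2.74-fold), with a two-sided exact permutation p of 0.0857 over 70 assignments. With wild type pool 1 left out the wild type mean was 3.28 ± 0.34 (SD, n = 3), the difference was -1.79 (3.46-fold), and every knockout pool lay below every wild type pool. The exact permutation p was then 0.0286, the smallest that 35 assignments can give. Neither difference passed the test over all genes (limma adjusted p = 0.735, and 0.364 without wild type pool 1). The array holds 1 probe for Aldh1a2, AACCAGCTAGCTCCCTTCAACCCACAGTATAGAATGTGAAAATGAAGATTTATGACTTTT, on chromosome 9 at 71143931 to 71143990 (mm9). It was well above background in all 4 knockout pools. Whether it lies inside the deleted part of the gene could not be looked up.

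The genes that separated the groups most clearly were lower in the knockout pools, by larger amounts than the clearest higher ones. Kctd16, an auxiliary subunit of the GABA-B receptor, was well above background in all 4 wild type and in none of the 4 knockout pools, and was at least 5.92-fold lower when knockout values were raised to the lowest signal called above background on each array. The call in wild type pool 1 says little, as 87.6% of probes dim on the other 7 arrays were called above background there. The Kctd16 probe lies on chromosome 18 at 40690672 to 40690731 (mm9). Espn, an actin-bundling protein (chromosome 4, 151495230 to 151495289), had a log2 fold change of -3.10 ± 0.41 (SE, n = 4 per group). Ttyh1, a membrane protein of the tweety family, had -2.30 ± 0.34, Car9, a carbonic anhydrase induced by low oxygen, had -2.61 ± 0.40, and the secreted glycoprotein Stc2 had -2.48 ± 0.46. Among the higher ones were Dlx2, a homeobox gene of crest-derived mesenchyme, at 2.08 ± 0.47, and the secreted glycoprotein Scube1 at 1.63 ± 0.33. Rarb, a retinoic acid receptor whose own gene is a retinoic acid target (chromosome 14, 17263367 to 17263426), was at 1.31 ± 0.34, the keratin Krt20 at 1.06 ± 0.26, and Camk2n1, an inhibitor of calmodulin-dependent kinase, at 0.95 ± 0.24. These 10 genes were chosen for having their 4 knockout values on 1 side of the 4 wild type values, which 5.49% of all genes had. That choice also fixed their directions in the other 7 arrays, where only the sizes could change. There Kctd16 was at least 5.48-fold lower, with Espn at -3.17 ± 0.41, Ttyh1 at -2.17 ± 0.28, Car9 at -2.77 ± 0.36 and Stc2 at -2.14 ± 0.36. The higher ones were then Dlx2 at 1.78 ± 0.40, Scube1 at 1.46 ± 0.25, Rarb at 1.02 ± 0.14, Krt20 at 1.06 ± 0.17 and Camk2n1 at 0.93 ± 0.13.

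No gene passed the test. With limma, 0 of 24291 genes had an adjusted p under 0.05, the smallest adjusted p was 0.492 (Kctd16 and Espn), and 433 genes had an unadjusted p under 0.05, 160 higher and 273 lower, where 1215 would be reached by chance. Without wild type pool 1, 0 of 23670 genes passed, the smallest adjusted p was 0.217, and 2506 genes had an unadjusted p under 0.05, 1476 higher and 1030 lower, where 1184 would be reached by chance. The groups did not overlap in 1334 genes (5.49%; chance gives 2.86%), and in 2719 of the same 24291 genes (11.2%; chance gives 5.71%) without that pool. With arrays weighted by their quality (limma arrayWeights), 8 genes passed: 1 rose (Dapk2, a death-associated kinase, log2 fold change 1.75) and 7 fell. These 7 were Espn (-3.38), Car9 (-2.60), the keratins Krt42 (-1.91) and Krt19 (-1.83), Dpp6 (-1.82), Frmd3 (-1.05) and a transcript without a gene symbol. Dapk2, Krt42, Dpp6 and Frmd3 were chosen for naming after their values were seen. In simulated data with 200 changed genes, the test on 8 arrays recovered 0% of 2-fold and 29% of 4-fold changes. On 7 arrays, with wild type pool 1 left out, it recovered 48% and 86%. The median residual SD was 0.668 with that pool and 0.207 without it. The simulations gave all arrays the same noise, while in the data wild type pool 1 stood apart. The shares for 8 arrays are therefore only a rough guide to what the test could recover here. The limma p-values measure spread between pools, which cannot be told apart from spread between arrays, as each pool had 1 array. The p-values of camera at the preset correlation rest on spread between genes instead.

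**Figure D2:**
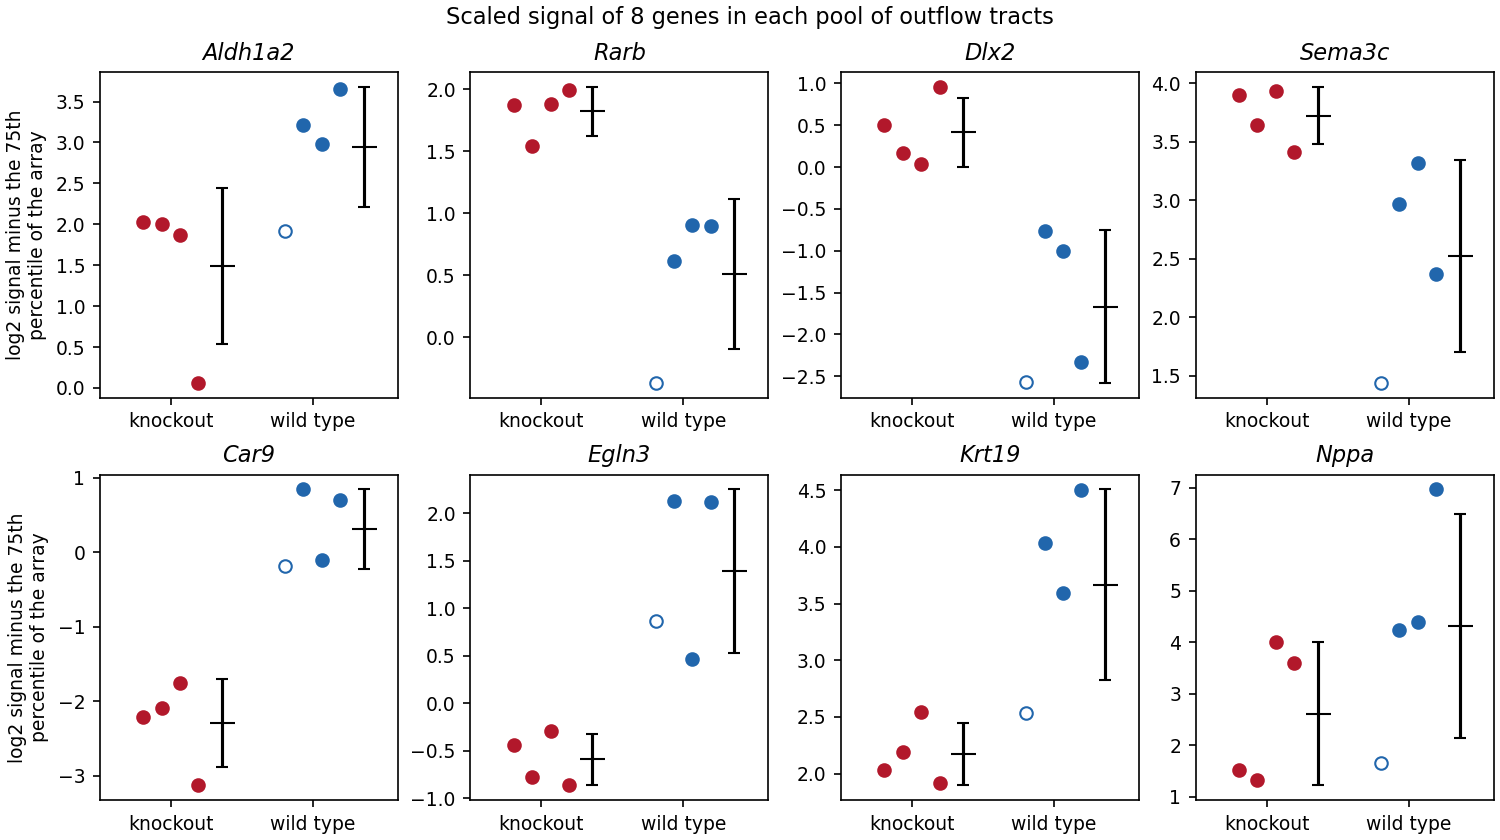
Log2 signal minus the array's 75th percentile of 8 genes in each pool, in red for the 4 knockout and in blue for the 4 wild type pools, with wild type pool 1 as an open circle; the bars give mean and SD over 4 pools. In Car9 the knockout mean was -2.29 and the wild type mean 0.32, without overlap.

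Genes of low oxygen and glycolysis fell in the knockout pools. The list had a median log2 fold change of -0.51 over 29 measured genes, 22 of them negative (limma camera adjusted p = 4.77e-09 with a preset correlation, adjusted p = 0.768 with an estimated correlation). Scaling by the array median moved the list median to 0.032, with the median over all genes at 0.67, and the test, which compares the list with the other genes, stayed lower (adjusted p = 5.47e-05). In the 7 arrays other than wild type pool 1 all 29 were negative, with a median of -0.74 (adjusted p = 9.55e-27, and adjusted p = 0.699 with an estimated correlation). No member passed over all genes, while 6 passed when adjusted over the list alone, and 23 without that pool. Besides Car9, the oxygen-sensing hydroxylase Egln3 had a log2 fold change of -1.99 ± 0.43 (SE, n = 4 per group), and -2.16 ± 0.42 without wild type pool 1. The mean of the list per pool was -0.36, -0.38, -0.22 and -0.68 in the knockout pools, with each gene centred on its mean over the 7 arrays other than wild type pool 1. This list mean was 0.65, 0.10 and 0.88 in wild type pools 2, 5 and 7, and -0.86 in wild type pool 1. An exact permutation test of these means gave p = 0.229 over 8 pools and p = 0.0286, the smallest possible, over 7. The second was 0.572 after adjustment over the 25 lists. A list that alone reaches the smallest possible p cannot pass that adjustment.

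The list of retinoic acid signalling and responsive genes rose, with a median of 0.46 over 27 genes, 22 of them positive (adjusted p = 0.00253, and adjusted p = 0.768 with an estimated correlation). Without wild type pool 1 the median was 0.27 with 18 of 27 positive (adjusted p = 0.0464, and adjusted p = 0.757 with an estimated correlation). When adjusted over the list alone, 0 members passed, and 3, all higher, without that pool. The pool means of the list overlapped between groups. They were 0.108, -0.039, -0.031 and 0.492 in knockout pools 1, 2, 3 and 7. In wild type pools 1, 2, 5 and 7 they were -0.788, 0.112, -0.270 and -0.372. An exact permutation test of these means gave p = 0.114 over 8 pools and p = 0.257 without wild type pool 1. Besides Rarb, the retinaldehyde reductase Dhrs3 had a log2 fold change of 0.90 ± 0.34 (SE, n = 4 per group), and Cyp26a1, which degrades retinoic acid, had 0.064 ± 0.82. Leaving out wild type pool 1, these were 0.69 ± 0.25 and 0.90 ± 0.46. Cyp26a1 was at -0.41 without wild type pool 7, and negative in 4 of the 8 fits that left out 1 pool. All 4 of these fits kept wild type pool 1, whose array had a raised signal on dim probes. The Cyp26a1 signal was -0.79 in that pool, against -4.72 to -3.44 in wild type pools 2, 5 and 7. It was well above background in only 2 of these 3. The Hox list, whose genes set position along the body axis, had a median of 0.77 over 15 genes (adjusted p = 0.132). It was called, higher, in 15 of 29 alternatives, among them when knockout pool 2 (adjusted p = 0.0128), wild type pool 2 (adjusted p = 0.0197) or wild type pool 1 was left out. The median was 0.19 (adjusted p = 0.576) without wild type pool 7 and 0.35 (adjusted p = 0.344) without knockout pool 7. With wild type pool 1 left out it rose, at 0.86 over 13 genes (adjusted p = 0.00791, and adjusted p = 0.757 with an estimated correlation), with 5 of 13 past the threshold when adjusted over the list alone. Hoxb4 had 1.74 ± 0.52, and 1.37 ± 0.43 without it.

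The second heart field list, of the progenitors that build the outflow tract, rose in 8 arrays, at 0.46 over 30 genes (adjusted p = 0.0188, and adjusted p = 0.768 with an estimated correlation), but had a median of 0.062 without that pool (adjusted p = 0.616); leaving out knockout pool 7 ended the call too (adjusted p = 0.0953). Its semaphorin Sema3c had 1.20 ± 0.42 (SE, n = 4 per group), and 0.84 ± 0.24 without it, and the T-box gene Tbx3 had 1.17 ± 0.45, and 0.81 ± 0.31. For the T-box gene Tbx1 the values were 1.33 ± 0.83 and 0.94 ± 0.87 (2.21 without wild type pool 2), for Isl1, a marker of these progenitors, 0.69 ± 0.39 and 0.53 ± 0.36, and for Hand2 0.90 ± 0.52 and 0.36 ± 0.18. Tbx2 was at 0.50 and 0.11, Wnt11 at 0.33 and 0.014, Fgf8 at -0.22 and 0.023, Fgf10 at -0.25 and -0.15, and Mef2c at -0.31 and -0.28. Scaling by the array median turned Fgf8, Fgf10 and Mef2c positive, as quantile and normexp scaling did for Fgf10, and moved the median over all genes from 0.13 to 0.67. The second heart field list shares 11 genes with other lists.

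Heart muscle genes changed direction with wild type pool 1, and with the scaling or weighting of the arrays. In 8 arrays the cardiomyocyte list had a median of 0.25 over 34 genes (adjusted p = 0.635). On the same 8 arrays it fell with quantile normalization (-0.149, camera adjusted p = 6.17e-08) and normexp (-0.163, camera adjusted p = 8.19e-09). With arrayWeights it fell too (-0.13, camera adjusted p = 0.000473). Without that pool it fell, at -0.18 with 30 of 34 negative (adjusted p = 1.75e-05, and adjusted p = 0.757 with an estimated correlation), and without wild type pool 7 it rose, at 0.49 (adjusted p = 0.0263). The natriuretic peptides Nppa and Nppb had log2 fold changes of -1.70 ± 1.09 and -1.71 ± 0.76 (SE, n = 4 per group), and of -2.59 ± 0.93 and -2.23 ± 0.70 without that pool. Leaving out wild type pool 7 gave -0.81 and -0.96. Myh7, a myosin heavy chain of heart muscle, had 0.34 ± 0.51 and -0.21 ± 0.13, and was negative with quantile and normexp scaling of 8 arrays too. Immediate early and stress genes had a median of 0.27, a mean of -0.090 and a downward test in 8 arrays (23 genes, adjusted p = 0.284). In the other 7 arrays they fell, at -0.29 (adjusted p = 8.06e-06, and adjusted p = 0.699 with an estimated correlation), with Ier3 at -1.78 ± 0.48 and Egr2 at -1.01 ± 0.43.

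Of 25 gene lists, camera with a preset correlation called 9 in 8 arrays, 8 higher and 1 lower, and 10 without wild type pool 1, 5 higher and 5 lower. In both fits 6 were called, 4 in the same direction (hypoxia and glycolysis lower; retinoic acid, erythroid and cell cycle genes higher) and 2 in opposite directions. The erythroid list rose, at 1.00 over 24 genes (adjusted p = 3.42e-06, and 0.63 with adjusted p = 0.0146 without that pool), and the cell cycle list rose, at 0.68 over 32 genes (adjusted p = 6.88e-06, and 0.17 with adjusted p = 0.00234). With an estimated correlation these had adjusted p = 0.768 in 8 arrays and adjusted p = 0.757 in 7. The erythroid median ran from 0.63 to 1.53 as each pool was left out, and its pool means overlapped, with knockout pool 3 at -0.48 and wild type pool 2 at 0.67. Extracellular matrix genes rose in 8 arrays, at 0.39 over 32 genes (adjusted p = 0.0163), and fell without that pool, at -0.090 (adjusted p = 0.0154). Ribosomal protein genes rose, at 0.48 over 33 genes (adjusted p = 0.00135), and fell, at -0.065 (adjusted p = 0.0119). Cushion mesenchyme genes rose, at 0.53 over 30 genes (adjusted p = 0.00557), and had -0.070 (adjusted p = 0.117). Smooth muscle genes rose, at 0.46 over 19 genes (adjusted p = 0.0178), and had 0.068 (adjusted p = 0.837). In these 4 lists wild type pool 1 had the lowest mean of the 8 pools, and no rise was called without that pool. Its means were -1.86 for extracellular matrix, -2.12 for ribosomal protein, -2.14 for cushion and -1.42 for smooth muscle genes. The ribosomal means of the other 7 pools ran from -0.17 to 0.19. With all 8 arrays kept, quantile normalization ended the matrix and ribosomal calls, at 0.045 and 0.031 with downward tests (camera adjusted p = 0.479 and 0.697). Normexp ended both too, at 0.055 and 0.024 with downward tests (camera adjusted p = 0.503 and 0.819). Leaving out knockout pool 3 ended the 8-array calls of the cushion (adjusted p = 0.0582), smooth muscle (adjusted p = 0.0787) and matrix lists (adjusted p = 0.0892), and leaving out wild type pool 7 ended that of smooth muscle (adjusted p = 0.0915). In all 4 lists the calls were lost with an estimated correlation (adjusted p = 0.768 in 8 arrays; adjusted p = 0.757 for the matrix and ribosomal lists in 7). In 7 arrays, without wild type pool 1, the neuronal list rose, at 0.35 over 18 genes (adjusted p = 0.0346, and adjusted p = 0.757 with an estimated correlation). By fry and by exact permutation of the pool means, 0 of 25 lists passed, with or without that pool. The permutation result decides little here. Its smallest possible p was 0.0286, so a list that alone reached it could not pass after adjustment over 25 lists.

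**Figure D3:**
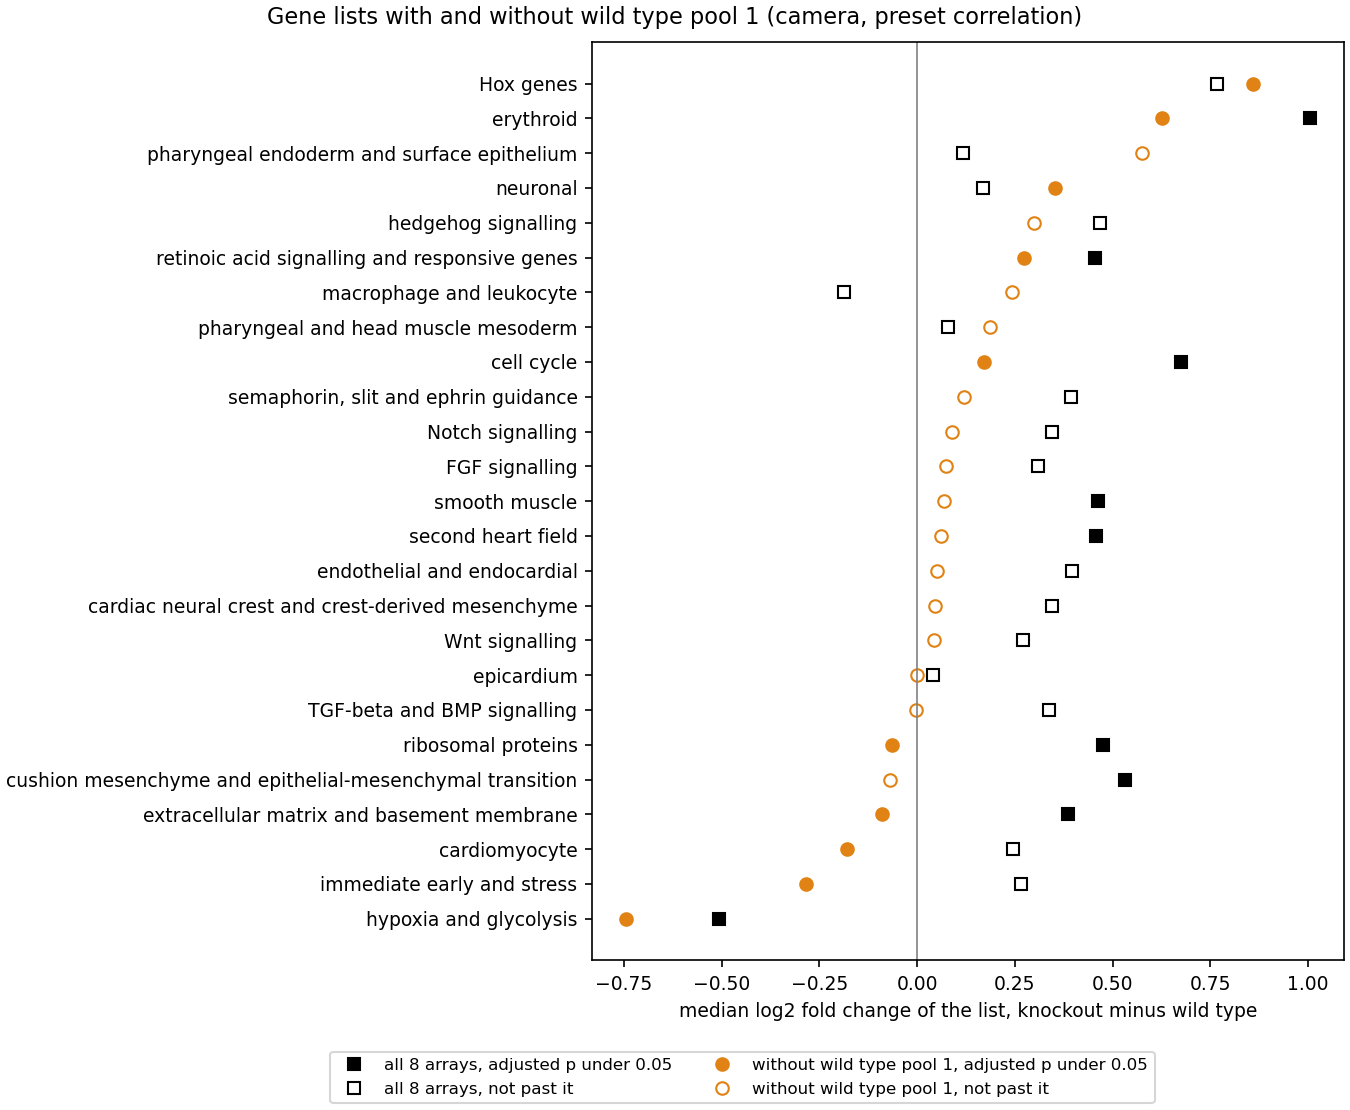
Median log2 fold change (knockout minus wild type) of the 25 gene lists in all 8 arrays (squares) and without wild type pool 1 (circles), filled where the adjusted p of camera with a preset correlation was under 0.05. Hypoxia and glycolysis lies lowest in both, at -0.51 and -0.74.

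The slide layout limits the whole comparison: all knockout arrays lay in row 1 of 1 slide and all wild type arrays in row 2, so row and genotype cannot be told apart. The knockout and wild type pools that share a number (1, 2 and 7) are not stated to be pairs and were treated as independent.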

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

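Of 212 groups of 4 pools checked for a pool far from the other 3, 28 had one, where chance gives about 1 in 20, or 10.6. The junction probe test and the counts of splits of the 8 arrays were written down before their results were seen, and leaving out each pool in turn had been decided before the data were examined; the other tests in this part were chosen after the result was seen. Wild type pool 1 was the pool apart in 3 array measures, 4 lists and 9 genes, and knockout pool 7 in 2 array measures, 1 list and 3 genes.

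The array of wild type pool 1 carried a raised signal on probes that were dim elsewhere. Its median processed signal was 2023 and its 75th percentile 4211, against 40.0 to 56.9 and 658.8 to 930.8 in the other wild type pools, and its negative control probes had 259.9, against 43.6 to 47.5. If the background of the slide were the source, the local background around the spots would lie above that of the other 7 arrays, but its median was 68, within 52 to 103. If genomic DNA left in the RNA were the source, dim probes that span an exon junction would lie below contiguous ones by at least 0.5, but 274 junction probes lay above 14625 contiguous ones by 0.338 (95% interval 0.192 to 0.484), and by -0.010 to 0.092 on the other arrays; which sign of the difference counts was settled in the calculation only after this value was seen, following the wording of the prediction. What remains open includes labelling or amplification of this sample, which could not be tested with these files, and no biological explanation was tested.

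The hypoxia and glycolysis list was lower in the knockout pools. The array of wild type pool 1 does not account for it, as the median without that array was -0.744. The hypoxia minus the cardiomyocyte list mean differed by -0.638 between groups (95% interval -1.21 to -0.064, 7 pools). This speaks against fewer cardiomyocytes only if their loss would shift both lists equally, which was not tested. The cardiomyocyte list mean itself differed by -0.313 (95% interval -0.885 to 0.259), so a contribution of fewer cardiomyocytes stays open. Chance cannot be excluded. Without wild type pool 1, 1 of 35 splits, the real one, gave the hypoxia list so small a camera p (3.82e-28, smallest other 1.65e-22). But the hypoxia list was singled out as the most extreme of 25. In 2 of 35 splits some list had a camera p as small (smallest other 7.46e-32). With all 8 arrays the real split was not the most extreme for the hypoxia list. Its camera p was 1.91e-10, and the smallest in another split was 5.52e-16. In 12 of the 35 splits of the 8 arrays, the real one among them, some list had a camera p as small as 1.91e-10. A difference in handling before lysis cannot be told apart from genotype, because with the immediate early list as a covariate the difference was -0.511 (95% interval -1.16 to 0.133), 53.7% of its size. Slide row and a real difference in oxygenation or in the genes' regulation may both account for it and stay untested.

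Genes near Aldh1a2 on chromosome 9 were examined for a flanking haplotype of the mutated locus. Without wild type pool 1, 13.57% of 199 genes within 10 Mb of the probe had an unadjusted p under 0.05, against 10.6% elsewhere (Fisher's exact p = 0.203) and a 95th percentile of 14.4% over windows elsewhere, and this cannot be told apart from chance. With all 8 arrays the share was 3.52%, against 1.71% elsewhere (Fisher's exact p = 0.0884), at the 96.9th percentile of windows. Without wild type pool 1 it was at the 88.8th. The share passed the 95th percentile only with that array, but neither Fisher test shows an excess. These values therefore cannot show that an excess rests on that array. Genes within the window, chosen after their values were seen, were Dapk2 (1.83 without that pool), Car12 (-2.29), Rora (-1.35) and Tex9 (0.80).

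For the count of genes past the threshold the splits decide nothing, since any split reaches the real count of 0 (35 of 35; highest other 1). Counts of genes at an unadjusted p under 0.05 do not exclude chance: 8 of 35 splits of the 8 arrays reached the real 433 (highest other 957), and 2 of 35 splits of the 7 arrays reached the real 2506 (highest other 2950). For the count of lists chance cannot be excluded: 29 of 35 splits gave at least the real count of 9, and the highest other was 17. Without wild type pool 1, 10 of 35 splits gave at least the real count of 10, and the highest other was 16.

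The other results that stood out follow as values. Knockout pool 7 had a median local background of 103 and negative controls at 117.4, against 59 to 60 and 45.5 to 52.3 in the other knockout pools. Its mean of the TGF-beta and BMP list was 0.13, and its Aldh1a2, Sox10 and Rgs5 values were 0.059, -2.99 and 2.68. Wild type pool 1 had list means of -0.744 for Wnt, -1.84 for cell cycle, -1.86 for extracellular matrix and -2.12 for ribosomal protein genes. Its gene values were 0.67 for Wnt11, 3.94 for Bmp4, 6.54 for Myh7, 1.29 for Etv5, 1.29 for Id1, 1.01 for Hey1, 0.61 for Cdk1, 5.84 for Rpl23 and 5.29 for Rpl27. Wild type pool 2 had 0.80 for Trim10 and 0.55 for Cx3cr1, and wild type pool 7 had -6.64 for Aurkb. Knockout pool 3 had 1.23 for Krt20, knockout pool 2 had -2.54 for Mrc1, and knockout pool 1 had -7.64 for Xist, which was -0.14 to 0.37 in the other knockout pools. The Y-linked Eif2s3y and Ddx3y had their highest values of the 8 pools in knockout pool 1, at 2.32 and 0.84.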

How the results depend on the processing

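The alternatives that leave out wild type pool 1 together with another choice, or with knockout pool 7, and the exact permutation of list means were chosen after seeing the data. Aldh1a2 was lower in all 24 alternatives that gave a value, from -1.82 to -0.91 (limma adjusted p 0.227 to 0.867), and from -1.79 to -0.98 when each pool was left out in turn. The mean of a gene's probes changes nothing for Aldh1a2, which has 1 probe. The count of genes stayed at 0 except for 8 with arrayWeights and 1 without wild type pool 1 and knockout pool 7, and was 0 to 0 when each pool was left out; the cause was not tested. The count of lists was 9 as reported, 6 to 13 when each pool was left out, and 18 (17 higher, 1 lower) with no filter on dim probes. It was 0 with an estimated correlation, with fry and with exact permutation, each with and without wild type pool 1. An estimated correlation allows for the members moving together. Exact permutation could hardly call a list after adjustment, as its smallest possible p is too large. Quantile normalization gave 5 lists higher and 2 lower, normexp 5 and 2, arrayWeights 4 and 3, and without wild type pool 1 there were 5 and 5. The median over all genes was 0.13 as reported, 0.20 with quantile normalization, 0.67 with median scaling and -0.30 with no filter. With median scaling the median of the hypoxia and glycolysis list was 0.032 while its test stayed lower (adjusted p = 5.47e-05); over its 29 alternatives the list kept its direction in 29 and passed in 25, with adjusted p up to 0.768. The retinoic acid list kept its direction in 29 and passed in 24. With pool number as a block (pools 1, 2 and 7) there were 0 genes and 12 lists, and Aldh1a2 was at -1.57. Deviations of pools with the same number correlated at -0.15, 0.32 and -0.41 across genes. These values cannot decide whether the pools are paired, as they are few and 1 rests on the array of wild type pool 1. Of 725 list values under alternatives, 575 kept their side of the threshold (521 also the direction, 54 in the other direction with neither value past the threshold), 62 lost a call, 49 gained one and 39 changed direction with a call in at least 1 of both. Of 2141 gene values 2134 kept their side (2076 also the direction, 58 in the other direction without a call) and 7 gained a call. The 54 were macrophage 15, TGF-beta and BMP 8, endothelial, head mesoderm and Wnt 6 each, cardiomyocyte 5, pharyngeal endoderm 3, epicardium and neuronal 2 each and hedgehog 1. Signal over background limits all values of dim genes.

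The lists that changed direction with at least 1 of both values past the threshold were, as medians and with the cause not tested: with quantile normalization, cardiomyocyte -0.149, extracellular matrix 0.045 and ribosomal 0.031 (downward tests); with normexp, -0.163, 0.055 and 0.024 (downward tests); with arrayWeights, cardiomyocyte -0.13, cushion -0.010, matrix -0.070 and ribosomal -0.045; without wild type pool 1, -0.179, -0.070, -0.090 and -0.065, the same with trend and robust, and for the last 3 also with an estimated correlation and with fry, where the cardiomyocyte list was lower too, without a call in either. When each pool was left out in turn these 4 lists ran from -0.179 to 0.488, from -0.070 to 0.807, from -0.090 to 0.561 and from -0.065 to 0.707. With that pool left out, quantile normalization gave cardiomyocyte -0.14, cushion -0.085 and matrix -0.086, and normexp -0.154, -0.087 and -0.058. With arrayWeights and that pool left out they were cardiomyocyte -0.153, cushion -0.015, smooth muscle 0.017, matrix -0.073 and ribosomal -0.058. Without that pool and knockout pool 7 they were cardiomyocyte -0.129, cushion 0.051, matrix 0.027 (downward tests) and ribosomal -0.098.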

Other observations

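Lists of neural crest, endothelial, endoderm, head mesoderm, epicardium, macrophage and neuronal genes did not pass the test in the 8 arrays. The cardiac neural crest list, of cells that enter the outflow tract, had a median log2 fold change of 0.35 over 25 genes (limma camera adjusted p = 0.136, and 0.046 with adjusted p = 0.600 without wild type pool 1), with 1 member, higher, past the threshold when adjusted over the list alone. For each gene below the second value is that without wild type pool 1. Sox10, a crest gene, had -0.18 ± 0.43 (SE, n = 4 per group) and -0.27, and Ngfr 0.89 ± 0.39 and 0.59; quantile, median and normexp scaling turned Sox10 positive, as leaving out wild type pool 2 (0.14) or knockout pool 7 (0.083) did. The endothelial list had 0.40 over 30 genes (adjusted p = 0.0541, and 0.052 with a downward test and adjusted p = 0.797), with Gja4 at 0.89 and 0.65 and Fli1 at 1.06 and 0.43, and was called, higher, without knockout pool 1 (adjusted p = 0.00462), wild type pool 2 (adjusted p = 0.033) or wild type pool 7 (adjusted p = 0.0119). The pharyngeal endoderm list had 0.12 over 22 genes (adjusted p = 0.635, and 0.58 with adjusted p = 0.119), but its pool means ran from -1.15 to 1.57 in the knockout and from -1.41 to 1.59 in the wild type, and its median from -0.54 to 0.58 as each pool was left out, with Grhl3 at 0.99 and 0.72. The head muscle mesoderm list had 0.079 over 10 genes (adjusted p = 0.618, and 0.19 with a downward test and adjusted p = 0.837), with Nkx2-6 at 0.67 and 0.59. The epicardium list had a median of 0.040, a mean of -0.057 and a downward test over 16 genes (adjusted p = 0.491, and 0.00 with adjusted p = 0.112), with Krt19 at -1.50 ± 0.43 and -1.87, and Cav1 at -1.04 ± 0.66 and -0.44. The macrophage list had -0.19 over 19 genes (adjusted p = 0.618, and 0.24 with adjusted p = 0.600), with Mrc1 at 0.71 and 0.35 and Cx3cr1 at 0.69 and 0.53 (1.21 and 1.15 without wild type pool 2). Neuronal genes in 8 arrays had 0.17 over 19 genes (adjusted p = 0.618), with Stmn3 at 0.92 and 1.01 and Stmn2 at 0.96 and 0.58.

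Signalling lists were on the positive side in 8 arrays and between -0.002 and 0.30 without wild type pool 1. FGF signalling had 0.31 over 21 genes (adjusted p = 0.491, and 0.075 with adjusted p = 0.399), with Il17rd at 1.08 and 0.68 and Etv5 at 0.81 and 0.26. TGF-beta and BMP signalling had 0.34 over 29 genes (adjusted p = 0.237, and -0.002 with adjusted p = 0.600), with Bmp6 at 0.78 and 0.39, Id1 at 1.04 and 0.43, Bmp4 at 0.73 ± 0.49 and Tgfb2 at 0.52 ± 0.57. Without that pool Bmp4 was at 0.21 ± 0.13 and Tgfb2 at -0.11 ± 0.14. Notch signalling had 0.35 over 20 genes (adjusted p = 0.136, and 0.090 with adjusted p = 0.600), with Hey1 at 0.95 and 0.43 and Jag1 at 0.79 and 0.36. Wnt signalling had 0.27 over 35 genes (adjusted p = 0.132, and 0.042 with a downward test and adjusted p = 0.695), with Wnt5b at 0.75 and 0.51 and Tcf7 at 0.55 and 0.45 (its lowest probe was at -0.34 and 0.27). Hedgehog signalling had 0.47 over 18 genes (adjusted p = 0.275, and 0.30 with adjusted p = 0.161), with Gas1 at 0.80 and 0.44 (its lowest probe was at -0.42 and -0.021). Guidance genes had 0.39 over 31 genes (adjusted p = 0.132, and 0.12 with adjusted p = 0.600), with Plxna2 at 1.08 and 0.59. Without wild type pool 2 the hedgehog and guidance lists were called, higher (adjusted p = 0.0261 each), and without knockout pool 2 the Wnt list was (adjusted p = 0.0433).

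Further members of the lists called in 8 arrays the erythroid Hbb-b2 at 1.33 and 0.87 and Trim10 at 1.25 and 1.11, and Cdk1 of the cell cycle at 0.92 and 0.49. The 3 probes of Cdk1 ran from -0.72 to 1.23, and from 0.055 to 1.11 without wild type pool 1. Of the smooth muscle list, Tes was at 1.32 and 0.92, Rgs5 at 0.97 and 0.57, and Acta2 at 0.39 and -0.12, negative with quantile and normexp scaling too. Of the cushion mesenchyme, Prrx1 was at 0.71 and 0.62 and Msx1 at 0.55 and 0.23. Of the extracellular matrix, Col14a1 was at 0.81 and 0.40 (lowest probe -0.82 and 0.13) and Tnc at 0.46 and 0.25 (lowest probe -0.13 and 0.25). Rpl23 was at 0.57 and 0.094 and Rpl27 at 0.57 and 0.043. Genes chosen after their values were seen were Adm at -1.87 ± 0.52 and -2.19, Ndrg1 at -2.40 ± 0.58 and -2.58, Stc1 at -1.77 ± 0.40 and -1.69, and on the retinoic acid side Crabp2 at 1.59 ± 0.66 (SE, n = 4 per group) and 1.20. Of the sex-linked genes, Eif2s3y had 0.58 ± 0.57 and 0.067, and Ddx3y 0.34 ± 0.54 and -0.048.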
